A study of Mus musculus with 11 samples.

How the data were processed

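Messenger RNA was sequenced from mouse pituitary cells isolated by fluorescence-activated cell sorting. Per the labels' protocols, sorted cells were frozen, RNA was extracted with a micro-scale column kit, amplified with a SMARTer kit and enriched for poly(A), and libraries were sequenced as 150-base read pairs on an Illumina NovaSeq. The labels assign 5 libraries to the APC-mutant genotype and 6 to wildtype. Replicate numbers come from the sample titles, where the mutant libraries carry the numbers 1, 2, 4, 5 and 6 and the wildtype libraries 1 to 6. The labels do not say whether libraries came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. The labels state neither the age of the animals, nor the sorting gate, nor the meaning of the word Lef1 in the mutant titles.

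The deposited values are raw fragment counts per gene, made per the file headers with featureCounts 2.0.1 over the GENCODE M33 gene annotation of the GRCm39 genome. Per the submitters' processing notes, Trim Galore 0.6.5, STAR 2.7.9a, featureCounts and DESeq2 were used, with no settings given there. Per the file headers, read pairs were counted without a strand option, a pair overlapping several genes was counted for each of them, and pairs that mapped to several places were not counted. A gene that shares exons or an antisense partner with another gene therefore includes that gene's fragments, and near-identical copies such as globin, heat-shock, kallikrein and hair keratin-associated genes lose fragments or can exchange them. Where at least 10% of the exonic bases of a gene described singly overlap another gene, the share is given once beside its values, a cut-off chosen after the values were seen. The deposited table holds 56941 genes for 11 libraries. The header of the table names 30 alignment files, of which only the 11 with a column are used here. Gene symbols were matched by identifier for 51948 identifiers, or 91.2%, which carry 98.61% of all counts. Coordinates are those of the deposited table, on GRCm39.

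Total counts ranged from 15740857 to 27280761 per library. A gene with no count in a library could have had up to 3 counts, which corresponds to 0.114 to 0.198 CPM depending on the library. Such floors and the 95% intervals of count ratios cover counting error only, because amplified fragments without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise. The chi-square statistic per degree of freedom ranged from 14.2 to 94.4 over pairs within a genotype.

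Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by the trimmed mean of M-values (TMM), and genotype was tested with the quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are APC-mutant minus wildtype. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are TMM-normalised CPM, counts scaled to a common library total, given as mean ± SD over 5 mutant and 6 wildtype libraries. Where all libraries of a genotype had no count, the fold is a lower bound against 3 counts over that genotype. Where a genotype had few counts, the ratio of normalised totals is given with its counting interval.

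The 24 gene lists, the tests, the rule for naming genes and the alternatives were set before the data were examined, apart from those named as later choices. The lists cover WNT targets, WNT ligands and receptors, the beta-catenin destruction complex, pituitary stem cell markers, endocrine lineage genes, the hedgehog, FGF, BMP and TGF-beta, and NOTCH pathways, tooth and enamel genes, keratins and stratified epithelium, senescence and the senescence-associated secretory phenotype (SASP), cell cycle, interferon-stimulated genes, YAP and TAZ targets, and extracellular matrix. Further lists hold markers of macrophages, neutrophils and lymphocytes, endothelium, mesenchyme and pericytes, posterior lobe and glia, and erythroid cells, as well as dissociation stress and mitochondrially encoded genes. Lists were tested with camera in limma 3.58.1, which asks whether members rank higher or lower than other genes, at a preset inter-gene correlation of 0.01. Adjustment was over the 24 lists. The same test with a correlation estimated per list is given beside it.

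The rule named Apc and Lef1, then the 6 largest and 6 smallest log2 fold changes. These came from called genes with a mean of at least 5 CPM and non-overlapping genotypes, leaving out predicted Gm genes, names ending in Rik and identifiers without a symbol. From each list the rule took the 2 members with the smallest p, or up to 4 where more passed. Fgf8, Sox2, Sox9, Axin2, Cga, Tshb, Il6, Dspp, Pomc, Pou1f1, Hesx1, list members that ran against their group, and the genes named in the closing observations were chosen after their values were seen. Some genes named by the rule are not reported singly here, and these are counted in their lists.

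Alternatives set in advance were DESeq2 size factors, library size without composition correction, no filter, a filter of 1 CPM in at least 5 libraries, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, each part of the wildtype libraries by name prefix, each library left out in turn, and for lists fry and an estimated correlation. Added after the data were seen were a fit without 3 libraries that stood apart from their group and a fit with the level of the Y-linked gene Eif2s3y as a covariate. The name prefix JS belongs to all 5 mutant libraries, ROSAJC to 4 wildtype libraries and ROSAE to 2, so a batch tied to the mutant prefix and the genotype cannot be separated.

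The edgeR and camera steps were tested on simulated counts before use, with 5 libraries against 6 and 19297 simulated genes passing the filter. Of genes changed by 1.5-fold, 13.4% of 67 were recovered, of those changed by 2-fold 40.3% of 67, and of those changed by 4-fold 78.8% of 66. Among 106 calls, 9 or 8.5% fell on unchanged genes. The list whose 22 members were raised 2-fold was found, and 0 of the other lists passed. Simulated genes varied independently of each other, and only 200 genes beside the list were changed. The simulation therefore does not test camera on correlated members, or the scaling of libraries when most genes change. Figures were drawn with matplotlib.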

Results

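To find genes that differ with the genotype label, transcript levels were compared between sorted mouse pituitary cells labelled APC-mutant and wildtype. APC is a scaffold protein of the beta-catenin destruction complex. The series summary calls the wildtype cells stem cells, but Gh, a gene of hormone-producing cells, took the largest share of counts in 5 of the 6 wildtype libraries. The data comprised 5 APC-mutant and 6 wildtype libraries. Total counts per library ran from 18082332 to 27280761 in the mutant group and from 15740857 to 25414443 in the wildtype group. After filtering, 20622 genes were tested with edgeR's quasi-likelihood test.

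Apc itself was measured first (ENSMUSG00000005871.16, chromosome 18, 34353977 to 34455605, GRCm39). Its level was 45.6, 41.5, 42.4, 37.8 and 44.5 CPM in APC-mutant replicates 1, 2, 4, 5 and 6. In wildtype replicates 1 to 6 it was 39.3, 39.5, 47.4, 46.6, 40.2 and 46.4 CPM. The log2 fold change was -0.03 ± 0.10 (SE, adjusted p = 0.819). Counts are summed over the whole gene, and the part of the gene that is altered is not given in the sources used here, so the level does not check the genotype label. Lef1, a transcription factor that partners beta-catenin and is named in the titles of the mutant libraries (ENSMUSG00000027985.15, chromosome 3, 130904120 to 131018005), stood at 133, 71.8, 100.2, 110.7 and 82.8 CPM in the mutant libraries. It stood at 6.42, 10.4, 10.03, 9.73, 9.33 and 17.9 CPM in the wildtype libraries. The rise of 3.23 ± 0.23 log2 units (SE) passed the test, with an adjusted p of 4.1e-08, and 13.8% of its exonic bases overlap another gene.

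The transcriptomes of the mutant and wildtype cells differed widely. Of the tested genes, 12218 (59.2%) were called, 6341 higher and 5877 lower in the mutant cells. A change of at least 1 log2 unit was found for 3987 of the higher and 3585 of the lower genes. For 8868 genes (43%) all mutant libraries lay on one side of all wildtype libraries, where chance gives 0.43%. The first principal component held 76.4% of the variance and separated the genotypes. Spearman correlations were 0.957 to 0.986 within and 0.785 to 0.817 between genotypes. Against the 4 ROSAJC wildtype libraries alone 11911 genes were called, and against the 2 ROSAE libraries alone 10652. All mutant libraries carry a name prefix of their own, so a batch tied to that prefix cannot be told apart from the genotype.

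**Figure D1:**
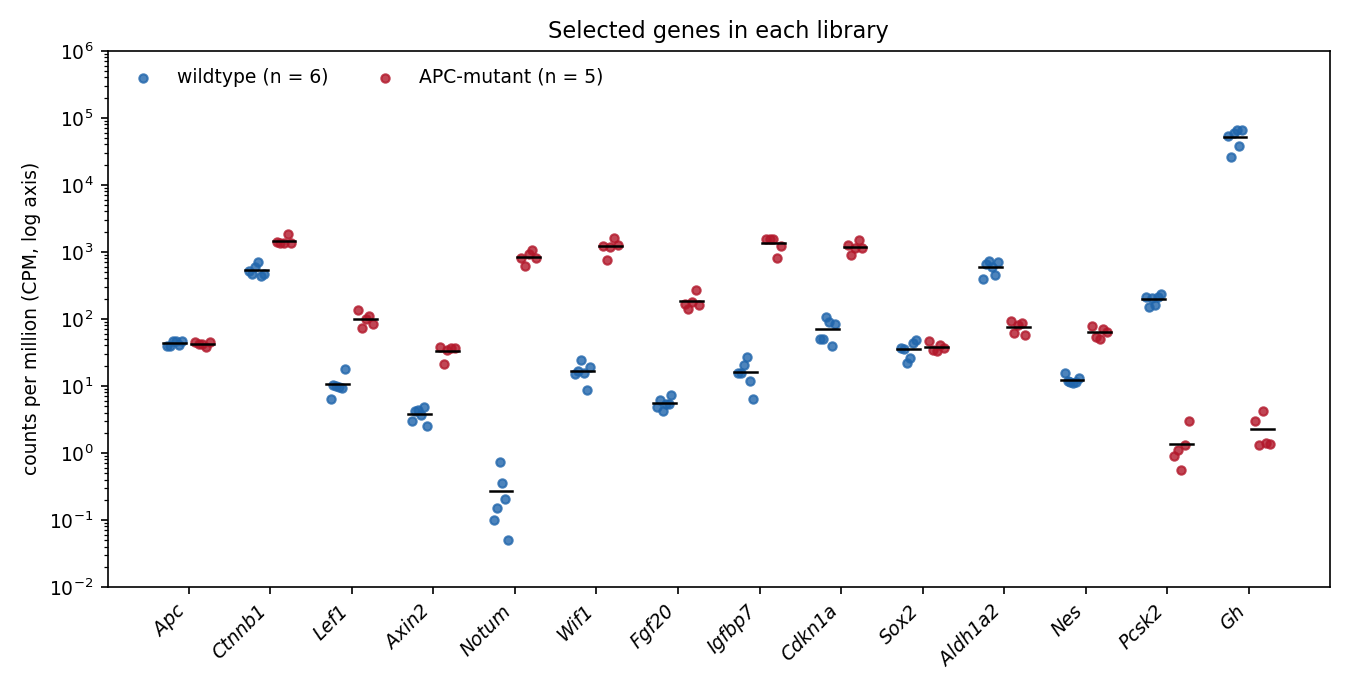
CPM (log axis) of 14 genes in each library, wildtype in blue (n = 6) and APC-mutant in red (n = 5), with black bars at the group means. Apc and Sox2 overlap between genotypes, the WNT-related genes Lef1, Axin2, Notum and Wif1 lie higher in every mutant library, and Gh falls from a mean of 51190 to 2.28 CPM.

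Of the 6 largest rises in the edgeR fit, 4 were in hair keratin and keratin-associated protein genes. This ranking depends on the fit, because the log2 fold change of a gene without wildtype counts has no fixed value. Under voom Krtap3-1, Krt31 and Krt83 rose by 9.88, 9.84 and 9.26, less than Fgf3 at 10.47. Prr9, a proline-rich protein gene (chromosome 3, 92029511 to 92031254), rose to 188 ± 79.2 CPM (SD, n = 5), and its normalised total was 10900 times that of the wildtype cells, where 2 counts leave a 95% counting interval of 3010 to 89900. The hair keratin Krt33a (chromosome 11, 99902021 to 99907038) reached 101 ± 45.1 CPM, a ratio of 6210 with an interval of 1720 to 51300. Krtap3-1 (chromosome 11, 99456853 to 99457456), Krt31 (chromosome 11, 99937472 to 99941377), Krt83 (chromosome 15, 101383011 to 101389393) and the alkaline phosphatase gene Akp3 (chromosome 1, 87052695 to 87055634) had no count in any wildtype library. They were at least 1640-, 1180-, 892- and 1320-fold higher in the mutant cells. The level of Krtap3-1 varied from 1.99 to 92.6 CPM between mutant libraries, and hair keratins and keratin-associated proteins have close paralogs, so the split between copies is uncertain. Adjusted p-values of these 6 genes lay between 1.74e-10 and 8.01e-05.

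The 6 largest falls included 2 hormone genes. Gh, encoding growth hormone (chromosome 11, 106191097 to 106192691), fell from 51190 ± 16140 CPM (SD, n = 6) to 2.28 ± 1.32 CPM (SD, n = 5), with an adjusted p of 1.26e-10. Prl, encoding prolactin (chromosome 13, 27241553 to 27249188), fell from 309 ± 172 CPM to 3 counts over the 5 mutant libraries, all in APC-mutant replicate 1, a ratio of 11200 with an interval of 3830 to 54200. Ghrhr, encoding the receptor for growth hormone-releasing hormone (chromosome 6, 55353280 to 55365515), fell from 269 ± 97.1 to 0.0544 ± 0.0958 CPM (-12.25 on the log2 scale, -13.86 without APC-mutant replicate 4). Klk1b26 (chromosome 7, 43661592 to 43666392), AC134546.1 (chromosome 18, 72818982 to 72858138) and Mettl21e (chromosome 1, 44243230 to 44258121) had no count in any mutant library and were at least 761-, 601- and 570-fold lower. Klk1b26 belongs to a kallikrein family of near-identical genes, so its share of the reads is uncertain.

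WNT target and feedback genes rose as a group. Of 22 tested members 19 rose and 1 fell, with a median of 3.29 log2 units, and 20 rose when adjusted over the list alone. Apcdd1, a WNT inhibitor at the membrane, rose by 7.56 ± 0.19 log2 units (SE) from 2.73 to 514 CPM. The secreted WNT inhibitor Wif1 rose by 6.18 ± 0.27 to 1209 ± 314 CPM, the transcription factor Sp5 by 6.93 ± 0.27 and Axin2 by 3.15 ± 0.21. Notum, which removes a lipid from WNT proteins, rose by 11.73 ± 0.36 to 844 ± 165 CPM. Of its exonic bases 38.1% overlap the antisense gene Notumos, whose reads cannot be separated without strand. The gene that fell was Trabd2b, at -1.01. Its call ended when any of APC-mutant replicates 4, 5 and 6 or wildtype replicate 4 was left out, with values of -0.98, -0.80, -0.98 and -0.83. The list passed camera at an adjusted p of 1.24e-19, and at an adjusted p = 0.0297 with an estimated correlation. In the same libraries endothelial markers made up 0.594% of mutant and 0.0057% of wildtype counts.

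Among WNT ligands and receptors 21 of 36 rose and 6 fell, with a median of 1.38 (22 rose and 6 fell adjusted over the list alone). Wnt6 rose by 6.99 ± 0.33 and Wnt10a by 5.59 ± 0.41 log2 units (SE), and the receptor genes Fzd4 and Fzd6 by 2.59 ± 0.15 and 2.01 ± 0.15. The camera test gave an adjusted p of 0.000307, and an adjusted p = 0.126 with an estimated correlation. The destruction complex list did not pass (adjusted p = 0.79, and adjusted p = 0.85 with an estimated correlation). Of its 12 members 2 rose and 3 fell, with the same counts adjusted over the list alone. Ctnnb1, encoding beta-catenin, rose by 1.47 ± 0.14 from 528 ± 100.5 to 1461 ± 200 CPM, with 15.1% of its exonic bases inside another gene. Apc2, Dvl1 and Dvl3 fell, with log2 fold changes of -2.06, -0.74 and -0.53. The products of Dvl1, Dvl2 and Dvl3 act against the complex, so the list mixes opposite roles. In the same libraries mesenchymal markers took 0.309% of mutant and 0.0241% of wildtype counts.

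The markers of pituitary stem cells and progenitors moved both ways. Of 25 members 6 rose and 13 fell, with a median of -0.51 (7 and 13 adjusted over the list alone). Sox2, a factor of pituitary stem cells, was 38.05 ± 5.69 CPM in mutant and 35.4 ± 10.1 CPM in wildtype libraries (log2 fold change 0.10, adjusted p = 0.66). Sox9 was 93.9 ± 30.5 and 58.2 ± 26.6 CPM (0.69, adjusted p = 0.0543). Leaving out APC-mutant replicate 5 or 6 or wildtype replicate 1 or 5 brought Sox9 past the threshold, with values of 0.81, 0.78, 0.85 and 0.85. Nes, encoding an intermediate filament of progenitors, rose by 2.35 ± 0.14, and Hesx1, a factor of the early pituitary primordium, by 3.49 ± 0.40. The retinoic acid-synthesising enzyme gene Aldh1a2 fell by 2.95 on the log2 scale, from 587 ± 137 to 75.8 ± 16.5 CPM. Cyp2f2, a cytochrome P450 gene with 13.5% of its exonic bases inside another gene, fell as well (-3.56). The list did not pass camera (adjusted p = 0.0833, and adjusted p = 0.491 with an estimated correlation). It passed at an adjusted p of 0.0181 against the ROSAE wildtype libraries, at 0.0271 without a filter and at 0.0368 without 3 libraries that stood apart (wildtype replicates 2 and 5 and APC-mutant replicate 5). Endocrine lineage genes took 8.18% of wildtype counts beside these markers. Endothelial markers and mesenchymal and pericyte markers had median rises of 6.77 and 3.68 in the same comparison, and the cells in which Nes rose are not known.

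Endocrine lineage genes, which mark hormone-producing cells, were high in the wildtype libraries. They took 8.18% of wildtype and 0.124% of mutant counts. Of 22 members 21 fell and 1 rose, also adjusted over the list alone, with a median of -5.71. Pomc, the precursor of adrenocorticotropic hormone, fell from 21080 ± 6899 to 79.3 ± 56.5 CPM, and the lineage factor gene Pou1f1 from 307 ± 135 to 0.389 ± 0.298 CPM. Neurod4 and the prohormone convertase gene Pcsk2 fell, at -9.32 and -7.14 on the log2 scale. Tshb and Cga, encoding subunits of glycoprotein hormones, fell as well (-5.35 and -3.09), and 31.97% of the exonic bases of Cga overlap another gene. Gata2, a factor shared by thyrotropes, gonadotropes and blood and vessel cells, rose by 1.93 ± 0.35, and by 3.21 against the ROSAE libraries alone. The list passed camera at an adjusted p of 5.6e-18, and at an adjusted p = 0.0261 with an estimated correlation.

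Signalling genes of the FGF family contained some of the steepest rises. Of 21 members 14 rose and 3 fell, with a median of 1.38 and the same counts adjusted over the list alone. Fgf3 reached 45.3 ± 11.4 CPM against 1 wildtype count, a ratio of 5420 with an interval of 972 to 214000, and its chromosomal neighbour Fgf4 reached 57.1 ± 19.6 CPM. Fgf20 rose by 5.03 ± 0.20 to 183 ± 51.6 CPM, Fgf8 by 5.58 ± 0.83 and the feedback inhibitor gene Spred1 by 1.55 ± 0.13. The wildtype level of Fgf8 came mostly from wildtype replicate 5 (4.97 CPM, next 1.40), and without that library the rise was 7.23. Etv1 and Fgf2 fell (-0.84 and -0.64). Of the exonic bases of Fgf20 and Fgf2, 12% and 13.2% overlap another gene. Fgf10 fell by 2.94 ± 1.16 (SE), from 51.9 ± 71.4 CPM. Its wildtype level came mostly from wildtype replicates 1 and 5 (132.3 and 154.3 CPM). Wildtype replicates 2, 3 and 4, at 1.06, 1.06 and 5.16 CPM, lay within or below the mutant range of 1.41 to 13.55 CPM. The mean of the posterior lobe and glial list was also highest in wildtype replicates 1 and 5, at 3.68 and 3.57 log2 CPM. It was 0.56 to 2.27 in the other wildtype libraries, and a link to Fgf10 was not tested. The Fgf10 call ended without APC-mutant replicate 1, 4, 5 or 6 or wildtype replicate 1 or 5 (-3.0, -2.96, -2.67, -2.78, -2.41 and -2.22). That of Fgf2 ended without APC-mutant replicate 2 or 4 (-0.57 and -0.58). The list passed camera at an adjusted p of 1.13e-05, with an adjusted p = 0.127 at an estimated correlation. Endothelial, mesenchymal and erythroid marker lists rose in the same comparison, as given with those lists.

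BMP and TGF-beta genes rose for 18 of 24 members and fell for 2, with a median of 1.95 and the same counts adjusted over the list alone. Bmp4 rose by 5.17 ± 0.28 to 175 ± 32.2 CPM, Tgfb1 by 4.77 ± 0.27, and the response genes Id3 and Smad7 by 2.86 ± 0.17 and 3.10 ± 0.20. Bmp6 and the BMP antagonist gene Chrd fell (-1.55 and -2.03). For this list camera returned an adjusted p of 5.39e-07 and an adjusted p = 0.11 with an estimated correlation. In the hedgehog list 10 of 14 rose and 2 fell, also adjusted over the list alone, with a median of 1.15. Shh, encoding a hedgehog ligand, rose from 0.155 ± 0.218 to 10.3 ± 2.50 CPM, and Sufu by 1.21 ± 0.13. Dhh rose by 5.73 ± 0.72, and 25.2% of its exonic bases and 15.7% of those of Shh lie inside another gene. Without wildtype replicate 2 the rise of Shh went from 5.83 to 6.80, and without wildtype replicate 4 that of Dhh was 7.28. Gli2 and Cdon fell (-1.41 and -0.75). The hedgehog list passed at an adjusted p of 0.0385, but not with an estimated correlation (adjusted p = 0.144), without APC-mutant replicate 1 (median 1.16, adjusted p = 0.0541) or with the Y-linked covariate (adjusted p = 0.0523). Mesenchymal markers took 0.309% of mutant counts beside these groups, against 0.0241% in wildtype.

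Genes of tooth development rose for 13 of 19 tested members, with 0 falls and a median of 3.85 (14 adjusted over the list alone). The median was 5.38 with the stricter filter and 5.41 against the ROSAE libraries alone. Msx2, a homeobox gene of the enamel organ, rose by 10.54 ± 0.42 log2 units to 84.9 ± 21.8 CPM (11.54 without wildtype replicate 2). Trp63, a regulator of stratified epithelia, rose by 6.17 ± 0.42 and Sp6 by 6.06 ± 0.41, although 86.7% of the exonic bases of Sp6 overlap another gene. Ambn, encoding an enamel matrix protein, reached 9.20 ± 3.77 CPM against 1 wildtype count, a ratio of 1110 with an interval of 198 to 43700. Dspp, encoding the dentin matrix precursor, had no wildtype count and was at least 489-fold higher. In the same libraries mesenchymal markers had a median rise of 3.68. Members left untested for low counts were Amelx, Enam, Amtn, Odam, Dlx1, Dlx6 and Barx1. The list mean lay between -1.32 and -0.38 log2 CPM in the wildtype libraries. Members that low in wildtype cells pass the filter mainly through their mutant counts, so the tally of rises and falls is partly set by the filter. The list's camera test yielded an adjusted p of 2.09e-06 and an adjusted p = 0.126 with an estimated correlation.

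Keratins and other genes of stratified epithelium rose for 21 of 24 members and fell for 2, with the same counts adjusted over the list alone and a median of 2.71. Krt23 rose by 7.08 ± 0.46, the desmosomal cadherin gene Dsc3 by 4.68 ± 0.31, Perp by 2.83 ± 0.23 and Krt7 by 2.59 ± 0.20. The epithelial adhesion gene Epcam fell by 1.57, from 1044 ± 212 to 352 ± 45.2 CPM, and the claudin gene Cldn7 changed by -0.69. Camera gave an adjusted p of 1.18e-07 and an adjusted p = 0.144 with an estimated correlation. Mean levels of the endothelial list lay between 8.62 and 9.10 log2 CPM in the mutant libraries, and between 0.03 and 3.19 in the wildtype libraries.

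Senescence and SASP genes rose for 22 of 26 members and fell for 0 (23 and 0 adjusted over the list alone), with a median of 2.89. Cdkn1a, a cell cycle inhibitor, rose by 4.08 ± 0.26 log2 units from 69.98 ± 27.3 to 1184 ± 219 CPM, and the related Cdkn2b by 2.55 ± 0.25. The secreted binding proteins Igfbp7 and Igfbp6 rose by 6.39 ± 0.34 and 2.74 ± 0.19. The cytokine gene Il6 rose by 6.51 ± 0.77 to 21.01 ± 13.6 CPM (7.56 without wildtype replicate 1). Cdkn2a, Csf2, Mmp3, Mmp10 and Mmp13 were too low to be tested. For this list camera returned an adjusted p of 3.66e-05 and an adjusted p = 0.158 with an estimated correlation. Macrophage markers rose in the same libraries, at 0.133% of mutant and 0.00496% of wildtype counts, and dissociation stress genes were at 0.983% and 0.525%.

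Cell cycle genes rose for 25 of 28 members and fell for 0, also adjusted over the list alone, with a median of 0.94. Ccne1 rose by 1.62 ± 0.15, the replicative helicase genes Mcm3 and Mcm6 by 1.28 ± 0.16 and 1.01 ± 0.12, and Top2a by 1.17 ± 0.17. The list's camera test yielded an adjusted p of 0.00156 and an adjusted p = 0.5 with an estimated correlation. Interferon-stimulated genes rose for 18 of 19 members and fell for 0, also adjusted over the list alone, with a median of 2.65. Ifi44 rose by 3.68 ± 0.22, Rsad2 by 3.42 ± 0.22 and Bst2 by 4.30 ± 0.28. Their camera test gave an adjusted p of 5.99e-08 and an adjusted p = 0.136 with an estimated correlation. Macrophage and endothelial markers, given with their lists, were higher in the same libraries.

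NOTCH pathway genes rose for 11 of 15 members and fell for 2 (12 and 2 adjusted over the list alone), with a median of 0.97. The ligand gene Dll4, used by sprouting endothelium, rose by 4.74 ± 0.32, Jag1 by 2.81 ± 0.32 and the receptor gene Notch1 by 3.02 ± 0.32. Dll3 fell by 4.81 on the log2 scale, from 94.7 ± 24.3 to 3.34 ± 1.46 CPM, and Notch2 changed by -0.71. The list passed at an adjusted p of 0.0394, but not with an estimated correlation (adjusted p = 0.158). It also missed the threshold without APC-mutant replicate 1 (median 0.91, adjusted p = 0.0535), without wildtype replicate 2 (median 1.0, adjusted p = 0.0544) and with the stricter filter (adjusted p = 0.0502). In the YAP and TAZ list 10 of 14 rose and 2 fell, also adjusted over the list alone, with a median of 1.36. Beside targets the list holds the pathway's own genes Yap1, Wwtr1 (encoding TAZ), Tead1 and Tead2, so the tally does not measure target output alone. Crim1 rose by 2.36 ± 0.17, Wwtr1 by 2.48 ± 0.24, Ajuba by 1.78 ± 0.17 and Lats2 by 2.66 ± 0.23, with 42.4% of the exonic bases of Lats2 inside another gene. Tead1 and Nuak2 fell (-0.73 and -0.69). Endothelial markers took 0.594% of mutant and 0.0057% of wildtype counts beside both lists. Camera gave an adjusted p of 0.00517 and an adjusted p = 0.308 with an estimated correlation.

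Extracellular matrix and basement membrane genes rose for 19 of 23 members and fell for 1, also adjusted over the list alone, with a median of 2.96. The collagen IV genes Col4a1 and Col4a2 rose by 4.82 ± 0.23 and 4.72 ± 0.21, Nid2 by 4.52 ± 0.23 and the laminin receptor gene Itga6 by 3.43 ± 0.18. Tnc fell by 0.91. For this list camera returned an adjusted p of 2.91e-11 and an adjusted p = 0.0536 with an estimated correlation. Endothelial and mesenchymal cells also express basement membrane genes, and their markers took 0.594% and 0.309% of mutant counts.

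**Figure D2:**
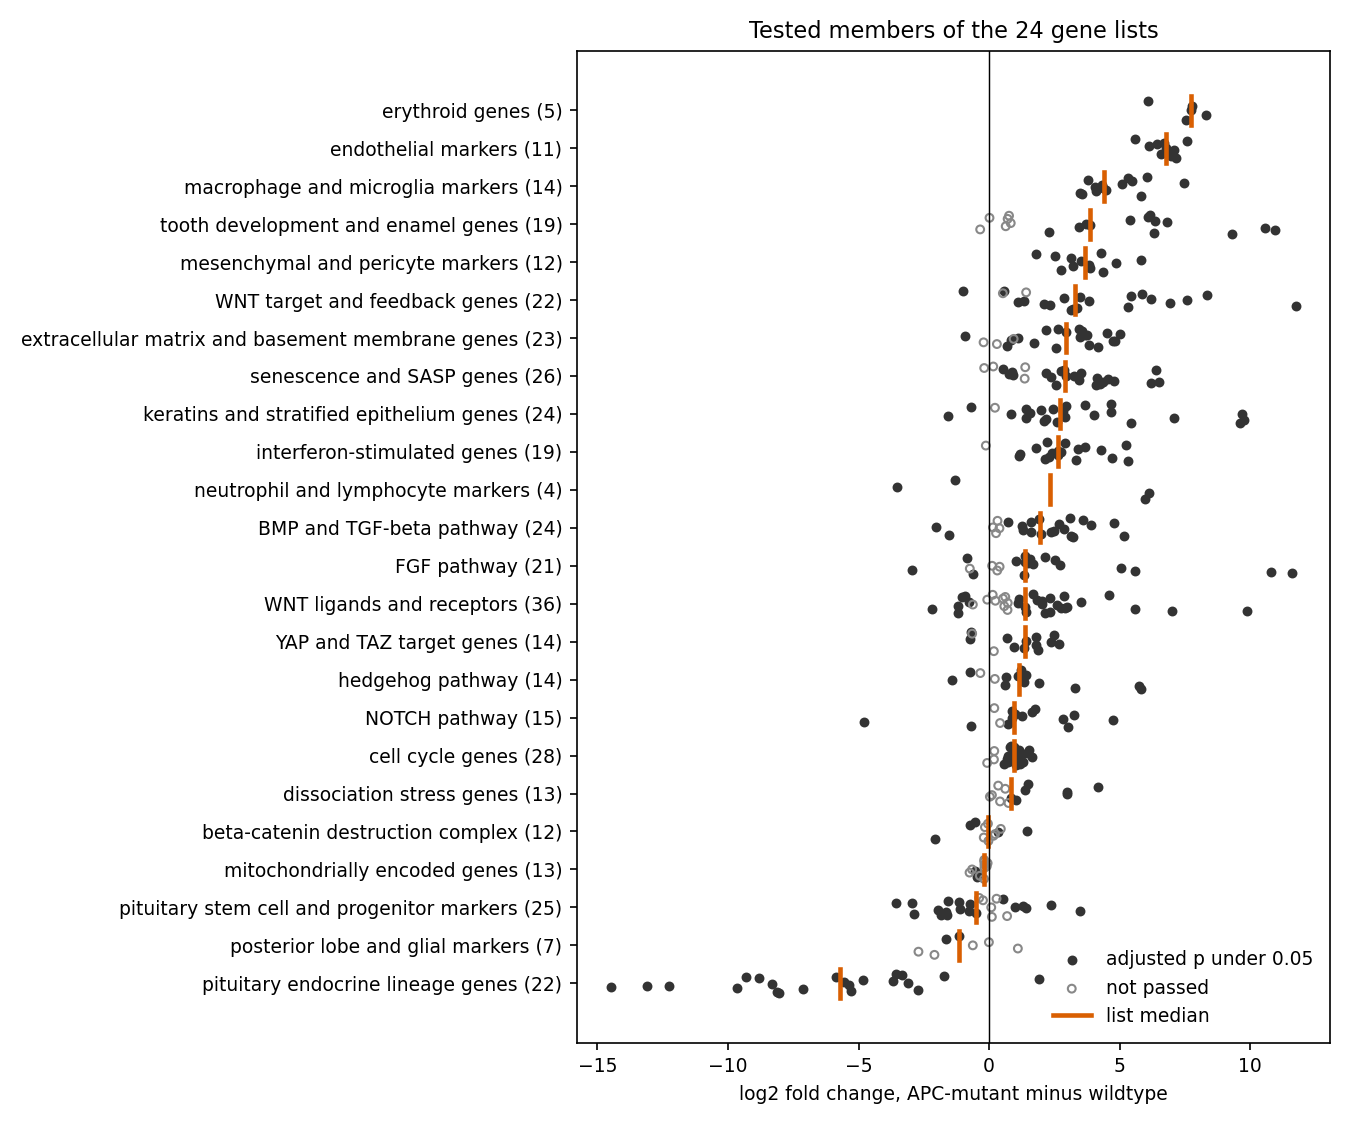
Log2 fold change (APC-mutant minus wildtype) of each tested member of the 24 lists, with the number of tested members in brackets. Filled points passed an adjusted p under 0.05, open points did not, and orange bars mark list medians, which run from -5.71 for endocrine genes to 7.74 for erythroid genes.

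Markers of other cell types were higher in the mutant libraries for most lists. All 11 endothelial markers rose, with a median of 6.77 (8.53 against the ROSAE libraries alone). Pecam1 rose from 2.96 ± 2.29 to 419 ± 63.4 CPM, Kdr by 6.59 ± 0.36, Tek by 6.69 ± 0.42 and Egfl7 by 5.60 ± 0.34 log2 units. All 5 erythroid genes rose, with a median of 7.74 and 0.322% of mutant against 0.00161% of wildtype counts. Hba-a1 rose by 7.74 ± 0.74 to 1322 ± 308 CPM, Hba-a2 and Hbb-bt by 7.79 ± 0.58 and 8.30 ± 0.59, and Alas2 by 6.08 ± 0.36. Of the exonic bases of Egfl7 and Alas2, 11.2% and 15.5% overlap another gene. The globin copies are near-identical and their split is uncertain. All 12 mesenchymal and pericyte markers rose, with a median of 3.68, among them Mgp by 4.28 ± 0.37, Dcn by 3.53 ± 0.19, Col1a1 by 4.37 ± 0.38 and Rgs5 by 5.80 ± 0.53. All 14 macrophage markers rose, with a median of 4.40 (5.10 against the ROSAJC and 3.68 against the ROSAE libraries alone), and Lyz2 reached 290 ± 208 CPM, Fcer1g 81.7 ± 67.4, Tyrobp 56.4 ± 45.2 and Cd68 41.6 ± 25.3 CPM. These counts were the same adjusted over the list alone. Adjusted p-values from camera were 8.49e-10 for endothelial, 0.000459 for erythroid, 1.5e-05 for mesenchymal and 0.00021 for macrophage markers. With an estimated correlation they were an adjusted p = 0.136, adjusted p = 0.158, adjusted p = 0.177 and adjusted p = 0.395.

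Of the neutrophil and lymphocyte markers 4 were tested, 2 rose and 2 fell, also adjusted over the list alone. S100a9 and S100a8, abundant in neutrophils, rose by 6.11 ± 0.71 and 5.96 ± 0.83, and the B cell genes Cd79a and Cd79b fell (-3.52 and -1.31). Cd79b (chromosome 11, 106202167 to 106205588) lies close to Gh (106191097 to 106192691), which also fell. Ly6g, Cd3d, Cd3e, Cd3g, Ms4a1 and Nkg7 were not tested, so a loss of B cells cannot be read from these falls. APC-mutant replicate 6 was highest for S100a9 and S100a8 (120 and 88.6 CPM), and without it the rises were 5.39 and 4.71. Without wildtype replicate 4 the rise of S100a9 was 6.70. The median of 2.32 and the mean of 1.81 were positive, while camera placed the list lower at an adjusted p of 0.875 (adjusted p = 0.922 with an estimated correlation). Of 7 posterior lobe and glial markers 2 fell and 0 rose, also adjusted over the list alone, with a median of -1.17 (adjusted p = 0.331, and adjusted p = 0.48 with an estimated correlation). Mbp was among those that fell (-1.17). The mean of the posterior lobe and glial list was 3.68 and 3.57 log2 CPM in wildtype replicates 1 and 5. It was 0.56 to 2.27 in the other wildtype libraries and 1.34 to 1.87 in the mutant libraries. Against the 2 ROSAE libraries alone Dvl3, Gli2 and Cd79b did not pass, at -0.48, -0.71 and -0.79.

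Dissociation stress genes, which respond to tissue handling, took 0.983% of mutant and 0.525% of wildtype counts. Of 13 members 7 rose and 0 fell, also adjusted over the list alone, with a median of 0.84. Ier3 rose by 4.18 ± 0.43, the heat-shock genes Hspa1a and Hspa1b by 2.99 ± 0.46 and 3.0 ± 0.53, and Dnajb1 by 1.38 ± 0.23. The Hspa1a and Hspa1b copies are near-identical and their split is uncertain, and 19% of the exonic bases of Hspa1a overlap another gene. The list did not pass camera (adjusted p = 0.0791, and adjusted p = 0.614 with an estimated correlation). It passed without APC-mutant replicate 5 (median 1.01, adjusted p = 0.0295), without wildtype replicate 6 (median 0.89, adjusted p = 0.0482), without a filter (adjusted p = 0.00632) and without the same 3 libraries (adjusted p = 0.0146). Of 13 mitochondrially encoded genes 3 fell (0 adjusted over the list alone) and 0 rose, with a median of -0.20 (adjusted p = 0.314, and adjusted p = 0.709 with an estimated correlation). These were mt-Nd5, mt-Nd2 and mt-Nd4, at -0.53, -0.47 and -0.48. Leaving out APC-mutant replicate 2 or 5 or wildtype replicate 1 or 3 ended all 3 calls (mt-Nd5 at -0.44, -0.45, -0.47 and -0.49, mt-Nd2 at -0.37, -0.39, -0.42 and -0.43, mt-Nd4 at -0.38, -0.42, -0.44 and -0.40). The mt-Nd2 and mt-Nd4 calls also ended without APC-mutant replicate 4 (-0.47 and -0.46) or wildtype replicate 5 (-0.46 and -0.44).

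**Figure D3:**
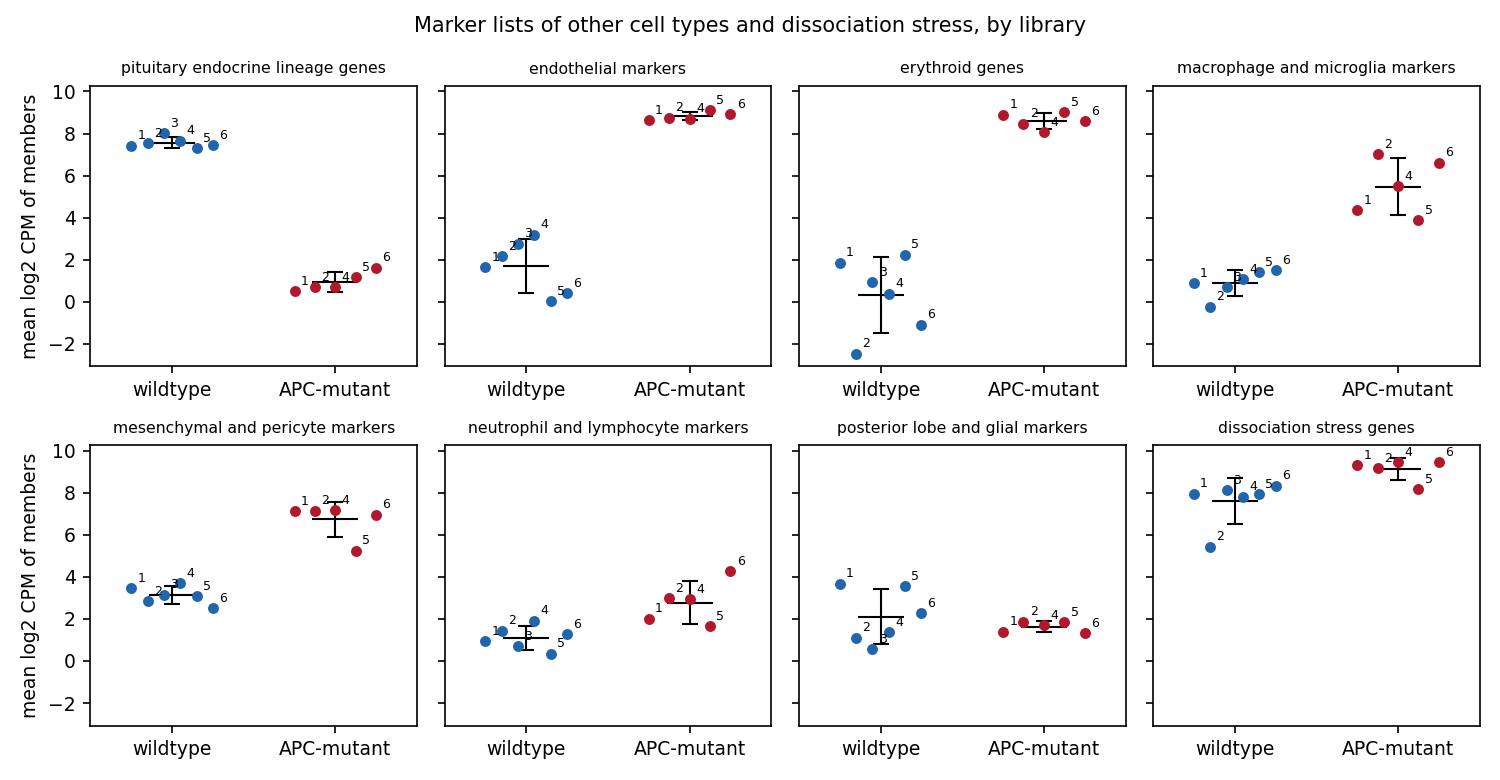
Mean log2 CPM of the members of 8 lists in each library, with replicate numbers beside the points, wildtype in blue (n = 6) and APC-mutant in red (n = 5), and black marks at the group mean ± SD. The endothelial list runs from 8.62 to 9.10 in mutant libraries, the macrophage list from 3.89 to 7.02, and the mesenchymal list is lowest in APC-mutant replicate 5, at 5.25.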

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

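The tests of senescence genes, of endocrine genes and of a shared dilution were chosen only after the result was seen, while the second marker lists and the regrouping of libraries were set before their results were seen. Values far from the rest of their group were sought among 358 sets of values, each a gene, a list mean or a library property within a genotype. The gap of the most extreme library was compared with Dixon's limit. Chance flags about 1 set in 20 of normally distributed values, or 18 here, and 33 were found. A gene with counts in only 1 library of a group is always flagged, so these numbers do not show an excess of outliers.

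In wildtype replicate 2, list means were low for dissociation stress genes (5.44 log2 CPM, next 7.82), senescence and SASP genes (0.74, next 2.2) and YAP and TAZ targets (4.13, next 4.97), and Ccne1 was high at 17.99 CPM. In wildtype replicate 5, Fgf8 was high at 4.97 CPM, Cdx1 at 0.363 CPM, and Fgf3 and Evx1 were each at 0.0518 CPM where the other wildtype libraries had none. Wildtype replicate 6 was high for Lef1 (17.9 CPM), Hspa1b (241 CPM) and Foxa2 (0.0492 CPM), and wildtype replicate 3 for Cga (3598 CPM) and Dmp1 (1.39 CPM). Wildtype replicate 4 was high for Dhh (0.360 CPM), Sp7 (0.120 CPM) and the embryonic globin gene Hba-x (0.06 CPM), and wildtype replicate 1 for Ambn (0.0501 CPM). Of these, Foxa2, Fgf3, Evx1, Ambn and Hba-x each rest on 1 count, and Sp7 on 2.

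APC-mutant replicate 5 stood apart most often. It was high for the embryonic globin genes Hbb-y (8.13 CPM, next 0.266), Hba-x (5 CPM, next 0.266) and Hbb-bh1 (2.14 CPM, next 0.356). It was also high for Ctnnb1 (1815 CPM), Fgf20 (272 CPM), Mcm3 (119 CPM) and Nnat (2295 CPM). It was low for Tgfb1 (39.3 CPM) and for the mean of mesenchymal markers (5.25 log2 CPM, next 6.96) and of dissociation stress genes (8.19, next 9.17). APC-mutant replicate 2 was low for Akp3 (22.6 CPM) and Axin2 (21.1 CPM), replicate 1 high for Prl (0.160 CPM, from 3 counts) and Wwtr1 (220.2 CPM), replicate 4 high for Ghrhr (0.221 CPM) and replicate 6 high for S100a8 (88.6 CPM).

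The count of 12218 called genes was compared with 99 other random splits of the 11 libraries into 5 and 6. Only 1 of the 100 splits, the real one, gave as many genes, the smallest share that 100 splits can give. This argues against a chance assignment of libraries, but a batch tied to the mutant name prefix would give the same result. The highest count in another split was 7544, in 1 of 2 splits that kept all mutant libraries together beside 1 wildtype library, and the median over the other splits was 0.

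Endothelial, erythroid, macrophage and mesenchymal markers were higher in the mutant libraries. A lower share of pituitary cells that raises every other type alike was examined by the spread of list medians. Medians of 5 lists, from erythroid (7.74) to posterior lobe (-1.17), spanned 8.91 log2 units. That was more than in any permutation of members (p = 1e-04, the smallest that 10000 permutations can give). The spread cannot decide the question, because a list whose wildtype level comes partly from the pituitary cells themselves would rise by less or fall. Wildtype levels summed over members were 16.12 CPM for erythroid and 150 CPM for posterior lobe genes, and the posterior lobe list did not pass camera (adjusted p = 0.331). Cells of each type in the mutant sort remain a possible source. On second marker lists that share no gene with the fixed lists, all 20 endothelial genes rose with a median of 6.30 (interval 5.81 to 6.78), 14 of 15 macrophage genes rose with 4.48 (4.13 to 5.02), and 13 of 14 mesenchymal genes rose with 2.23 (1.58 to 3.01), although Col6a3 fell from 57.1 to 16.2 CPM. The most abundant of these genes reached 1010 CPM (Cd34), 232 CPM (Cd83) and 317 CPM (Bgn), and 16, 11 and 14 of the lists' genes were also at 1 CPM or more in wildtype cells. Of 8 further erythroid genes only 4 could be tested and 2 rose, with a median of 4.42 (0.22 to 8.94), too few to tell erythroid RNA from another source, and expression of such genes by the mutant cells themselves, or a sort gate that differed, stays open and untested.

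Senescence and SASP genes rose in the same libraries as macrophage markers. Their list mean was lowest in the same library as that of dissociation stress genes in both genotypes, wildtype replicate 2 (0.74 and 5.44 log2 CPM) and APC-mutant replicate 5 (4.25 and 8.19). The macrophage list mean was lowest in these libraries too, at -0.23 log2 CPM in wildtype replicate 2 and 3.89 in APC-mutant replicate 5. Macrophages as the source of the arrest, lysosome and insulin-like growth factor binding protein genes are argued against. The 9 called members of that part had a median SD of 0.32 log2 units over the mutant libraries (interval 0.16 to 0.42), less than 0.68, which is 0.5 of the SD of the macrophage list mean. For the 13 called secreted factors and proteases the median SD was 1.2 (0.71 to 1.65), near the macrophage SD of 1.37, and 0.86 after the macrophage mean was subtracted. That part cannot be told apart from macrophage RNA, with 5 libraries to compare. For both parts endothelial or mesenchymal cells, a response to tissue handling and an effect of the genotype stay open and untested. The endothelial list mean varied little over the mutant libraries, from 8.62 to 9.10 log2 CPM.

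Endocrine genes fell in the mutant libraries. Dilution of all pituitary cells by other cells is argued against, since the median of the endocrine list lay -5.20 log2 units from that of the stem cell list (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). Loss of one fixed share of endocrine cells would lower genes found only in those cells by one factor. The 21 falling members had an SD of 3.54 log2 units, from -1.73 to -14.47, against a median standard error of 0.52. This spread cannot decide the question, because members also expressed in the remaining cells would fall by less. Unequal loss of endocrine cell types, endocrine RNA carried into the wildtype sort, and an effect of the genotype stay open and untested, as neither the gate nor cell counts are given in the sources used here.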

How the results depend on the processing

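All alternatives were set in advance except the fit without 3 libraries that stood apart (wildtype replicates 2 and 5, APC-mutant replicate 5) and the Y-linked covariate, which were chosen after seeing the data. The number of called genes ran from 10577 to 13867 over 22 alternatives, always within 1.5 times 12218. It was 11517 to 12094 with 1 library left out, 11991 without the 3 libraries and 11741 with the covariate. The share of calls that were higher in mutant cells ran from 47.9% to 54.5%, and 0 shared calls changed sign. At least 11307 calls were shared with the reported ones when 1 library was left out. The replicate block called 10577 genes (5662 higher, 4915 lower). Same-numbered libraries deviated together by correlations of 0.048, -0.13, 0.011, -0.059 and -0.049, and 0 mutant libraries correlated best with their own number, so the numbers are no evidence of pairing. The block brought the stress list past the threshold (1.04), turned camera's direction upward for neutrophil and lymphocyte markers (1.88), and ended calls on mt-Nd2, mt-Nd4, Trabd2b, Fgf2 and Fgf10.

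Of 528 list results in alternatives, 489 kept direction and side of the threshold, 21 lost their call and 11 gained one. In 7 more the direction turned without a call in either fit, all for neutrophil and lymphocyte markers or the destruction complex, and 0 called lists turned. The estimated correlation ended the call of 16 of 18 lists without moving their medians, because it widens the test. These were WNT ligands and receptors (1.38), hedgehog (1.15), FGF (1.38), BMP and TGF-beta (1.95), tooth (3.85), keratins (2.71), SASP (2.89), cell cycle (0.94), interferon (2.65), NOTCH (0.97), YAP and TAZ (1.36), matrix (2.96), macrophage (4.40), endothelial (6.77), mesenchymal (3.68) and erythroid (7.74). Its values for all lists stand in the report. The fry test asks whether members move one way on balance and compares them with no other genes. It called the stem cell (-0.51), posterior lobe (-1.17) and stress (0.84) lists and gave the destruction complex the opposite direction to camera at a median of -0.038. Without a filter the stem cell (-0.50) and stress (0.85) lists passed. Against the ROSAE libraries the stem cell list passed (-0.44). Without the 3 libraries the stem cell (-0.53) and stress (0.70) lists passed. Camera's direction for neutrophil and lymphocyte markers, a list that passed in no alternative run with camera, turned upward without a filter (3.26), against the ROSAE libraries (3.83), without the 3 libraries (3.16), and without APC-mutant replicate 5 or 6. The stricter filter ended the NOTCH call (0.96) and the covariate the hedgehog call (1.15). With 1 library left out, medians ranged from 1.10 to 1.24 for hedgehog, 0.90 to 1.10 for NOTCH, 1.59 to 3.51 for neutrophil and lymphocyte markers, and 0.64 to 1.01 for stress genes. Medians of called lists moved by over 1.5 times on the fold scale for tooth genes (5.38 with the stricter filter, 5.41 against the ROSAE libraries), endothelial markers (8.53 against the ROSAE libraries) and macrophage markers (5.10 against the ROSAJC and 3.68 against the ROSAE libraries), and these lists kept their calls there. The cause was not tested for any of these beyond the fewer samples or other genes that each alternative holds. Of 3138 results on 143 named genes, 3075 kept direction and side of the threshold, 51 lost their call, 9 gained one (Sox9 in each), 3 changed sign without a call (Sox2 at -0.27 and -0.006, Apc at 0.012) and 0 called genes changed sign. The lost calls were on Fgf10, mt-Nd2, mt-Nd4, mt-Nd5, Trabd2b, Fgf2, Gli2, Dvl3 and Cd79b. The fold of 50 named genes moved by over 1.5 times in at least 1 alternative, for 33 against the ROSAE libraries alone, for 24 under voom and for 18 when 1 library was left out. The largest such moves with 1 library left out were for Cdx1 (13.68 without wildtype replicate 5), Prl (-15.6 without APC-mutant replicate 1) and Sp7 (11.23 without wildtype replicate 4). Depth limits genes below about 0.114 to 0.198 CPM, where 3 counts cannot be told from none.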

Other observations

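The gene groups and genes in this part were chosen after their values were seen, and none was tested as a hypothesis. Hair keratins, keratin-associated proteins, and late cornified envelope and small proline-rich genes have 120 members in the deposited table, of which 90 had too few counts to be tested. Of the 30 tested members 29 rose and 0 fell. These were 15 of 15 hair keratins (median 8.66), 6 of 7 keratin-associated proteins (10.31) and 8 of 8 late cornified envelope and small proline-rich genes (9.63). For 27 of the 30 the wildtype mean was under 1 CPM. A gene that low in wildtype cells passes the filter mainly through its mutant counts, so this tally tests nothing, and close copies leave the split of reads uncertain. Ibsp, encoding bone sialoprotein, was at 75.3 ± 38.1 CPM (SD, n = 5) against 0.0898 ± 0.129 CPM (SD, n = 6), Dmp1 at 127 ± 92.3 against 0.409 ± 0.499 CPM, and the osteoblast factor gene Sp7 at 14.8 ± 3.93 CPM against 2 wildtype counts, a ratio of 893 with an interval of 247 to 7380. The log2 fold change of Ibsp went from 9.68 to 10.4 without wildtype replicate 4, and that of Dmp1 from 8.41 to 9.22 without wildtype replicate 3.

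Cdx1, a transcription factor that patterns the hindgut and posterior axis, was at 82.6 ± 21.9 CPM in mutant and 0.0605 ± 0.148 CPM in wildtype libraries, where all 7 counts were in wildtype replicate 5. Evx1 and Foxa2 were at 15.7 ± 4.11 and 15.1 ± 3.93 CPM against 1 wildtype count each, with ratios of 1900 (340 to 74900) and 1750 (314 to 69400), and Pax3 had no wildtype count and was at least 464-fold higher. Adjusted p-values for these genes lay between 5.15e-10 and 3.31e-07. The neighbouring imprinted genes Igf2 and H19 rose by 3.29 ± 0.19 and 3.35 ± 0.18 log2 units (SE), with 64.5% of the exonic bases of Igf2 inside another gene. Meg3 and Dlk1, which also neighbour each other, changed by -3.44 ± 0.35 and -2.26 ± 0.18, and Nnat by -3.92 ± 0.24, from 23850 ± 6803 to 1571 ± 406 CPM.

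Xist, expressed from the inactive X chromosome and with 12.6% of its exonic bases inside another gene, was 524 and 339 CPM in APC-mutant replicates 4 and 5, where the Y-linked gene Eif2s3y had no count. In APC-mutant replicates 1, 2 and 6 Xist was 0.213, 0.0509 and 0.203 CPM and Eif2s3y 83.1, 98.0 and 74.8 CPM. Wildtype replicates 2 and 4 held both, with Xist at 123 and 143 CPM and Eif2s3y at 36.2 and 49.1 CPM. Wildtype replicate 1 held Xist at 381 CPM and Eif2s3y at 1.10 CPM, while wildtype replicates 3, 5 and 6 held Xist at 268, 709 and 668 CPM and Eif2s3y at 0, 0 and 0.0492 CPM. No wildtype library was as low in Xist as APC-mutant replicates 1, 2 and 6, so these transcripts were not balanced between the genotypes.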
